A study of Mus musculus with 2 samples.

How the data were processed

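Chromatin accessibility was measured per cell by sci-ATAC-seq in 1 sample of mouse hippocampus and 1 sample of cultured hippocampal neurons, both from strain C57BL/6 per the labels. The culture medium was Neurobasal A with B27 and glutamax, per the labels' growth protocol. Each sample came with its own deposited table, and a joint table held the cells of both. Reads were aligned with BWA to mm10 and regions were called with MACS2, per the submitters' processing notes, and their versions, settings and read filters are not given in the sources used here.

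Each deposited table held whole-number read counts per region and cell, which were not normalised. There were 183566 regions in the joint table, 98043 in that of the tissue and 143437 in that of the culture. In the joint deposited table, an even number made up 77.5% of the nonzero counts, as when each end of a read pair is counted, so counting intervals were computed from fragments, taken as the reads divided by 2 and rounded up in each region and cell. The deposited tables also gave a fraction of reads within the called regions for each cell, a cluster name per cell, and a mark of fresh or frozen material for each tissue cell. Deposited deviation scores, named as chromVAR output per the file headers, gave a bias-corrected score per motif and cell, and per marker set of a cell type and cell, with no true zero, so differences and SDs were used and no folds. Deposited Cicero co-accessibility values between pairs of regions were listed for the tissue sample alone. Of 3160 cells in the joint table, 3160 were matched to a sample's own table by cell name, barcode and cluster name. The members of the marker sets are not given in the sources used here, and sets with a cluster number in place of a cell type were not used, nor were the deposited plot coordinates.

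The tissue sample had 2346 cells and 21162305 reads in regions of the joint table, and the culture sample 814 cells and 13205979 reads. No cell was removed for depth in the main analysis. The parts of each barcode taken as PCR indexes, from their place and length, fell into sets that shared no index among fresh cells. These sets were called A, B, C and D and used as a batch: fresh tissue cells were in A and B, frozen tissue cells in D, and culture cells in A, B and C. Cells were placed in a set by the last of the PCR indexes alone. Tissue and culture cells of a set thus need not share the other PCR index. What separated the sets is not given in the sources used here.

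A region belonged to a protein-coding gene where it overlapped the gene body or the 2 kb upstream of it in GENCODE vM21, which is on the same assembly as mm10. Of 21897 protein-coding genes 17322 had a region, 56.1% of regions lay in a gene, and 2.64% lay in 2 or more genes and counted for each. Reads were summed over the cells of a group, divided by all reads in regions and given as CPM. Ratios are log2 of CPM + 1, tissue over culture, and a pseudocount of this kind understates the ratio of low genes. Sums carry exact Poisson 95% intervals and shares of cells exact Clopper-Pearson 95% intervals.

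There were 15 lists of cell-type markers and 5 lists of genes of a shared process, called early genes, postsynaptic genes, neurite genes, channel genes and housekeeping genes in the text. Genes needed at least 50 reads over the groups compared. For each list the median log2 ratio was set among 10000 random lists of the same size matched on mean level, and its percentile is a description of these samples and no test. A list in the outer 2.5% on either side is said to stand apart. The interval of a list median came from 1000 Poisson draws of the fragments. Because each group had 1 sample, no p-value, standard error or number of changed genes was computed. Lists, markers, the comparisons, the alternatives listed first and the rule for the genes named were fixed before the data were examined.

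Genes named in the text were the 2 to 4 members of each list with the largest absolute ratio among those with at least 200 reads, with any opposite member needed to describe the list, the 10 genes with the highest and the 10 with the lowest ratio in each comparison, and the 5 regions with the highest and the 5 with the lowest ratio among regions with at least 100 reads. Other genes named, such as those that led clusters or had many links, were chosen after their values were seen. Some genes that the rule selects are not reported here.

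Cell classes came from the deposited cluster names, none of which spans both samples, each checked against the marker lists and its top 10 genes by ratio over the other clusters of its sample. The excitatory neuron-like class held tissue clusters NR1, NR2 and GRN and culture cluster VT1, the interneuron-like class held INT and VT2, and clusters CLL, NOI, VT3 and VT4 stayed unnamed. Own clusters served as an alternative. They came from TF-IDF over regions seen in at least 50 cells, components 2 to 30 of a truncated singular value decomposition, 20 nearest neighbours and Leiden clustering at resolution 1, and each took the deposited class of most of its cells. Doublets were predicted from 3160 simulated pairs: a cell was left out of the shares where over 70% of its 40 nearest neighbours were simulated. This marked 76 cells, 2.41% of all, and recovered 19.8% of 1545 simulated pairs of different classes, so most doublets will have stayed in. Sums of reads between the samples kept the marked cells.

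Several choices were made or altered after the data had been seen. These are the use of the deposited classes in place of own clusters and the naming of own clusters by those classes, the doublet threshold, which had been higher, the removal of VT4 from the excitatory neuron-like class, the limit of 0.05% of all reads for heavily read regions, and the comparison genes in the test of Gad2. The grouping of the deposited motif scores into 14 families was also made then. The limit that decides whether depth accounts for the AP-1 scores was made stricter after the result had been seen. The planned search for motifs in the regions' sequence was not run, because a genome sequence was not used here, and the deposited scores stand in its place.

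Alternatives were promoter regions only (within 2 kb of a transcription start), scaling by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed on each side), pseudocounts of 0.5 and 5, a minimum of 200 reads and no minimum, the share of cells with a read after thinning each cell to 1000 fragments, each sample's own table, doublets left out or kept, the lowest 20% of cells by depth left out, and other components (to 15 and to 50) and resolutions (0.5 and 2). Alternatives added after the data had been seen were fresh or frozen cells alone, index sets A and B alone, culture cells of index set B left out, VT3 and VT4 left out, CLL and NOI left out, VT4 added to VT1, dentate granule-like cells left out, and 8 heavily read regions left out.

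The calculations were tested on simulated data drawn from the real gene levels and depths. Fragments were independent Poisson draws, each counted as 2 reads, at rates shared by both groups except for planted genes. Variation between cells or index sets was not simulated, so the coverage of the intervals holds for such counts only. With all cells and 16996 genes, genes planted at 2-fold and 4-fold had median estimates of 0.96 and 1.98 on the log2 scale, and genes planted at 0.5-fold and 0.25-fold had −0.95 and −1.86. The 95% interval of unchanged genes held the true value in 94.8%, and 3.5% of 200 unchanged lists lay in the outer parts. With excitatory neuron-like cells and 16668 genes, the medians were 0.96, 1.97, −0.95 and −1.87, the intervals held the true value in 94.5%, and 6% of unchanged lists lay in the outer parts. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.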

Results

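Single-cell combinatorial indexing ATAC-seq, which tags open chromatin with combined barcodes so that reads can be assigned to single nuclei, was carried out on mouse hippocampus and on neurons cultured from it. There was 1 sample per group, so there are no replicates, and the intervals given with values cover counting error only. The tissue sample held 2346 cells with a median of 7171 reads in called regions per cell (quartiles 4417 to 11477). The culture sample held 814 cells with a median of 10933.5 (quartiles 4262 to 24208). A median of 32.8% of a tissue cell's reads and 37.6% of a culture cell's reads lay in called regions. Of the tissue cells, 1519 were marked fresh and 827 frozen.

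The comparison of cell makeup asked which hippocampal cell types the culture retained. Excitatory neuron-like cells made up 75.2% of 2293 tissue cells (exact Clopper-Pearson interval 73.4 to 77.0) and 31.7% of 791 culture cells (28.5 to 35.1). Interneuron-like cells made up 5.54% of the tissue (4.64 to 6.55) and 29.3% of the culture (26.2 to 32.6), with 23.1%, 45.9% and 17.5% in the culture's PCR index sets A, B and C and 19.5% without set B. Astrocyte-like, oligodendrocyte-like, oligodendrocyte precursor-like and microglia-like cells made up 5.32%, 6.59%, 2.57% and 1.88% of the tissue. The deposited clusters are specific to a sample, and no culture cluster had a glial name. The deposited scores for glial marker sets were low in the unnamed culture clusters VT3 and VT4. The Astrocyte set had −0.52 ± 0.65 (SD over cells) and −0.78 ± 0.74 there, against 4.77 ± 1.33 in the astrocyte-like tissue cluster AST. The Oligodendrocyte set had −0.25 ± 0.30 and −0.55 ± 0.45, against 5.31 ± 1.10 in the oligodendrocyte-like cluster OLI. The Microglia set had 0.03 ± 0.41 and −0.31 ± 0.53 there, against 3.12 ± 1.26 in the microglia-like cluster MRG. These are means of clusters, so single glia in the culture were not ruled out. The excitatory neuron-like culture cluster VT1 scored −0.93 ± 0.67 on the CA1_Pyramidal set, below AST at −0.47 ± 0.63. A low set score in culture therefore cannot show that a cell type is absent, and the class of VT3 and VT4 stays open. Unnamed clusters held 2.88% of the tissue and 38.9% of the culture (35.5 to 42.4), and the culture's share was 56.6%, 4.42% and 61.0% in sets A, B and C. Culture cells of set B were deeper, with a median of 25257 reads against 6428 in A and 5615 in C, and 49.7% of them were excitatory neuron-like, against 20.3% and 21.6%, or 21.1% without set B.

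The clusters behind these names were told apart by their markers. The tissue cluster GRN was the dentate granule neuron-like one: its granule list was 1.72 higher on the log2 scale than in the other tissue cells, and Prox1, a transcription factor of granule neurons, was among its top 10 genes with C1ql2 and Dsp. NR1 carried the CA1 pyramidal list (0.74), and NR2 had a small excess of the CA3 list (0.24), close to that of its endothelial or mural list (0.21) and microglia list (0.18). The deposited S1_Pyramidal set scored 0.69 ± 1.17 (SD over cells) in NR2, against −0.26 ± 0.83 in NR1 and 0.24 ± 0.76 in GRN. The CA1_Pyramidal set scored 0.54 ± 0.90 in NR2 and 1.24 ± 1.08 in NR1. The subtype of NR2 thus stays open. NR1 and NR2 had no listed marker among their top 10 genes and excitatory list excesses of 0.05 and 0.11. The other tissue cells in that comparison were mostly excitatory neuron-like themselves, so a small excess cannot decide the class. Slc17a7 was at 190 CPM (169 to 213) in NR1 and 147 CPM (137 to 158) in NR2 against 42.7 CPM (27.9 to 62.5) in INT. The deposited NEUROD motif scores were 1.12 ± 0.78 (SD over cells) in NR1 and 0.90 ± 1.17 in NR2, against −1.64 ± 0.86 in INT. The astrocyte-like cluster AST had Sox1 and no member of the astrocyte list among its top 10, with an astrocyte list excess of 2.26. GRN, NR1 and NR2 made up 32.0%, 11.9% and 31.3% of tissue cells. Tissue cluster INT and culture cluster VT2 had the vesicular GABA transporter gene Slc32a1 among their top 10 genes, and VT2 had the homeobox genes Dlx1, Dlx5 and Dlx6 there too. VT1, the excitatory neuron-like culture cluster, had Neurod1 among its top 10. Of the unnamed culture clusters, VT3 was led by Gm10720, Gm10715 and Gm10718 and had a median of 3927 reads per cell, against 25115 in VT1, and VT4 was led by Myo3a at 2.51. A median of 16.9% of a VT3 cell's reads and 28.4% of a VT4 cell's lay in called regions, against 45.6% in VT1 and 42.0% in VT2. VT3 and VT4 held 213 and 95 of the 791 culture cells.

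**Figure D1:**
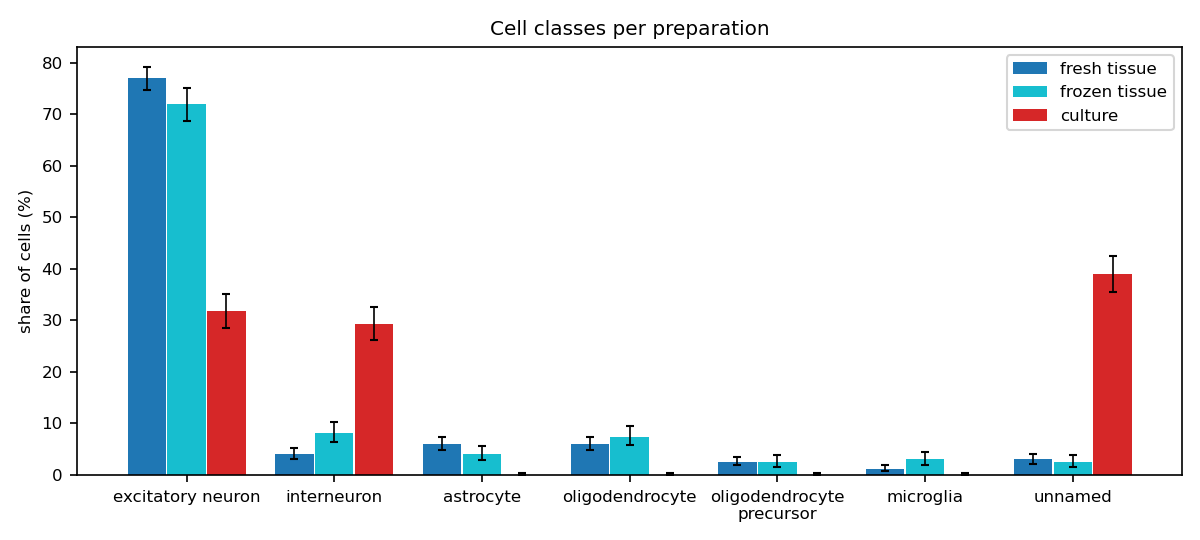
Share of cells in each class (%, vertical axis) for fresh tissue, frozen tissue and culture cells, with bars for exact 95% intervals. Excitatory neuron-like cells were 77.0%, 72.0% and 31.7% of the 3 preparations. The culture has no bar for glia because none of its clusters was named as glial, which does not rule out glial cells in it.

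**Figure D2:**
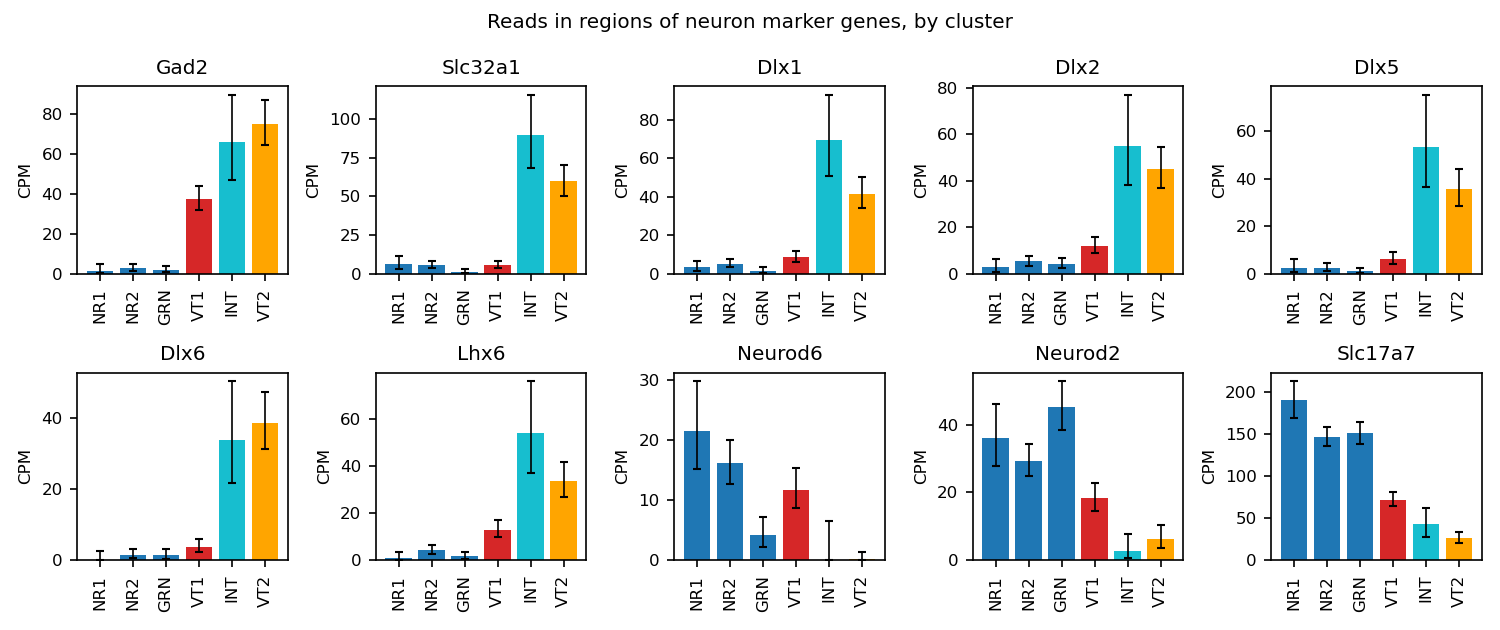
Reads in the regions of 10 neuronal marker genes, in CPM, for the neuronal clusters of the tissue (NR1, NR2, GRN, INT) and the culture (VT1, VT2), with exact Poisson 95% intervals. Gad2 was 37.5 CPM in VT1 and 75.2 CPM in VT2.

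The comparison over all cells asked how accessibility at genes of known cell types and processes differed between tissue and culture. Of 12 interneuron genes measured, 10 were lower in tissue, with a list median of −1.27 (−1.47 to −1.13) on the log2 scale, below all random lists (percentile 0). Gad2, which encodes a GABA-synthesising enzyme, had 6.24 CPM in tissue (4.90 to 7.83) and 48.5 CPM in culture (43.5 to 53.8), a log2 ratio of −2.77. Dlx6, Dlx5 and Lhx6, transcription factors of the interneuron lineage, had −2.03, −1.67 and −1.56, while Adarb2 (0.41) and Npas1 (0.13) were higher in tissue. The list median was −1.26 within index set A and −1.48 within index set B. The deposited Interneuron set scored 0.0215 ± 1.27 in tissue and 0.191 ± 1.43 in culture.

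Genes of oligodendrocytes were higher in tissue, with a list median of 0.61 (0.54 to 0.87, percentile 99.99) and 10 of 12 members above 0, or 12 of 12 with trimmed-mean scaling. They were led by Mobp (1.72) and Myrf (1.53), a myelin gene and a regulator of myelination. Of 12 housekeeping genes 11 were higher in tissue, with a median of 0.61 (0.49 to 0.68, percentile 99.6), and B2m turned from lower to higher with trimmed-mean scaling. Eef2, a translation factor gene, had 52.4 CPM in tissue and 27.5 CPM in culture. Genes lower in tissue also came from the endothelial or mural list (median −0.73, −0.97 to −0.52, 7 of 11 members), among them the vessel receptor gene Tek (−1.34), with Abcc9 (−1.10) and with Pdgfrb opposite at 0.90. The median of this endothelial or mural list ranged from −1.10 to −0.32 over the alternative settings. The deposited marker sets of these cell types scored the other way, with Endothelial at 0.354 ± 0.978 in tissue and −0.341 ± 0.852 in culture and Mural at 0.130 ± 0.904 and −0.209 ± 0.762, as 8 of the 9 sets named for a cell type were higher in tissue. The progenitor list was lower by its median as well (−0.76, −0.89 to −0.58, 7 of 10 members), with the transcription factor genes Sox1 (−1.10) and Sox2 (16.4 CPM in tissue and 33.7 CPM in culture), and with Hes5 opposite at 0.71. The Cajal-Retzius list had −0.93 (−1.16 to −0.46, percentile 2.14), with Reln at −1.28 and Trp73 opposite at 0.59, and stood apart in 9 of 16 alternative settings. With promoter regions alone the endothelial, progenitor and housekeeping lists no longer stood apart, and within index set A neither did the oligodendrocyte list, nor the housekeeping list within set A or B.

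The other lists lay among the random lists. Excitatory neuron genes had a median of 0.36 (percentile 89.0), with the synaptic kinase gene Camk2a at 200 CPM in tissue (192 to 209) and 74.7 CPM in culture (68.7 to 81.2), the glutamate transporter gene Slc17a7 at 136 and 55.1 CPM, and Neurod2 at 31.9 and 12.9 CPM. The CA1, CA3 and dentate granule lists had 0.36, 0.42 and 0.40, the pan-neuronal list 0.10, the astrocyte list 0.10, the microglia list 0.37 and the fibroblast list −0.52. The oligodendrocyte precursor and ependymal lists had −0.08 and −0.15 and turned to 0.19 and 0.12 with trimmed-mean scaling. Postsynaptic genes were higher in tissue for 15 of 16 members (median 0.36, percentile 89.2), led by Nrgn, with 65.8 CPM in tissue and 20.7 CPM in culture, and by Dlg4 (0.90), and Dlgap1 turned from lower to higher with trimmed-mean scaling. Early genes, which neuronal activity induces, had a median of 0.31 (percentile 55.1), with Arc (0.87), Jun (0.74) and Egr3 (0.66) higher and Fos lower, at 35.5 CPM in tissue (32.2 to 39.2) and 55.5 CPM in culture (50.4 to 61.1). Neurite genes went both ways (median 0.16): Igfbpl1 (−1.20), Dpysl3 (−0.84), Gap43 (−0.70) and Dcx (−0.61) were lower in tissue and Stmn1 (0.78) higher. So did channel genes (median 0.15), with Scn8a (0.71) and Cacna1e (0.51) higher and Kcnq5 (−0.63) lower. The median of all 16810 genes was 0.18, with 63.2% of genes higher in tissue, and trimmed-mean scaling moved these to 0.45 and 77.2%, so the lists are placed against random lists of the same samples.

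Among genes with at least 200 reads, the lowest in tissue included Lama1, a laminin gene (chromosome 17, 67697259 to 67822647, mm10), with 19.2 CPM in tissue (17.0 to 21.6) and 182 CPM in culture, a log2 ratio of −3.18. Slc17a8, a vesicular glutamate transporter gene (chromosome 10, 89574020 to 89621253), had 2.84 CPM in tissue (1.95 to 3.98) and 31.4 CPM in culture (27.5 to 35.8). Myo3a (−3.08), Timd2 (−2.99), Helt (−2.94) and Fam3b (−2.93) followed, but Myo3a and Timd2 had no promoter region with reads. The other 4 of the lowest 10 were the predicted genes Gm10718, Gm10720, Gm10801 and Gm10719, with −3.40 to −2.99. Gm10718, Gm10720 and Gm10719 also led VT3, where a median of 16.9% of a cell's reads lay in called regions. Gm10801 lay over 1 of the 8 heavily read regions. The ratios of these predicted genes need not reflect regulation of genes. The highest in tissue was Smim5 (chromosome 11, 115899966 to 115906269), with 20.1 CPM in tissue and 0.909 CPM in culture (0.392 to 1.79). Trim31 (3.14), Vsig2 (2.80), Pla2g2f (2.78), Chrm4 (2.56), Tmem54 (2.51), Krt9 (2.47) and Olfr535 (2.41) followed, and Il25 and Cmtm5, both at 2.54, shared 1 region.

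Single regions differed more than genes. The region with the lowest ratio lay within Gm36264 on chromosome 13 (9011531 to 9012367, mm10), outside its exons, and had 11 reads in tissue and 5786 in culture (−8.17). The next was on chromosome 15 (85177547 to 85178065) in no gene, with 4 and 992 reads, and the one after it on chromosome 18 (73533204 to 73533830), over the ribosomal RNA gene n-R5-8s1, with 5 and 981 reads. The others were on chromosome 2 (73012608 to 73013132, −5.07) and chromosome 4 (7391418 to 7392029, −4.96), in no gene. The highest ratio was at a Poc1a exon on chromosome 9 (106300225 to 106300830), with 551 reads in tissue and 9 in culture (4.01). Introns of Jdp2 on chromosome 12 (85610127 to 85610652, 3.92), Ddrgk1 on chromosome 2 (130657424 to 130658103, 3.85) and Zbtb16 on chromosome 9 (48803357 to 48804056, 3.83) and a region in no gene on chromosome 9 (43537040 to 43537884, 3.91) completed the highest 5.

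**Figure D3:**
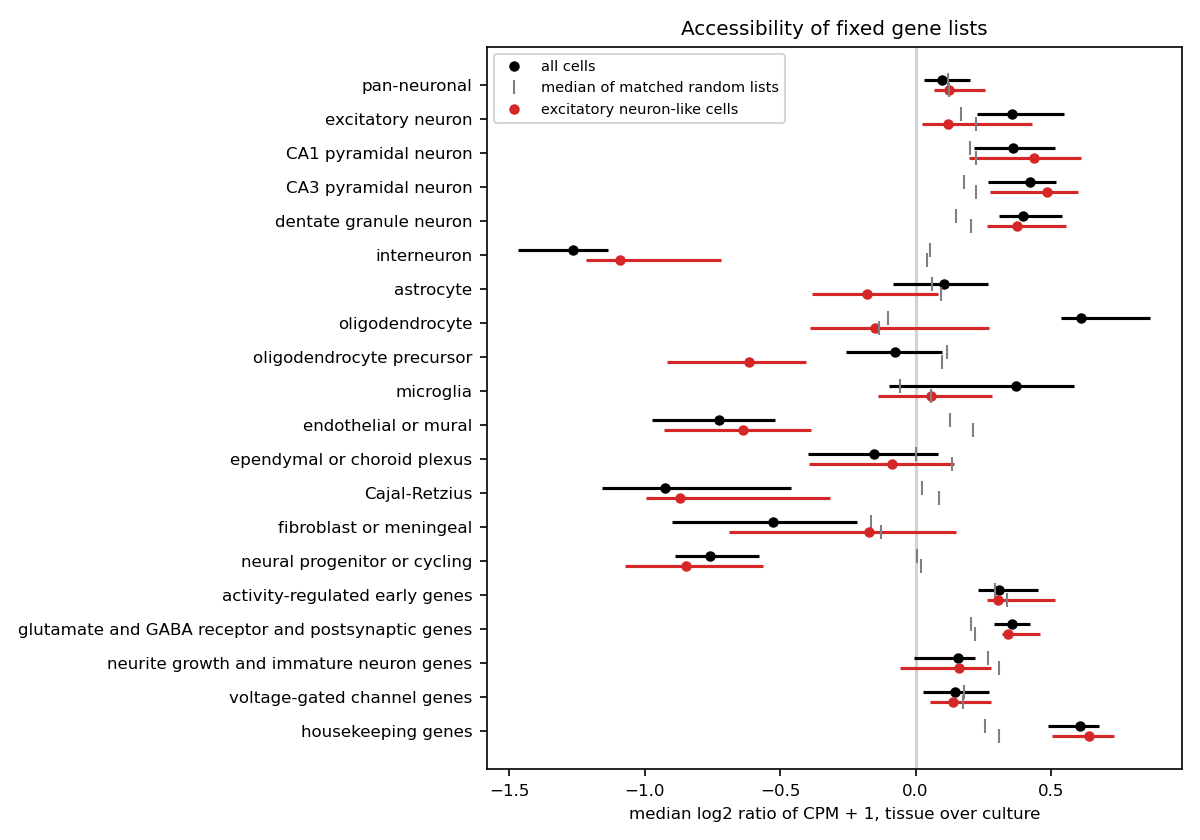
Median log2 ratio of CPM + 1, tissue over culture (horizontal axis), for each gene list, over all cells (black) and excitatory neuron-like cells (red), with counting intervals and grey ticks at the median of matched random lists. The interneuron list lies lowest in both, at −1.27 and −1.09.

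The comparison within excitatory neuron-like cells asked whether these differences stood in the main neuron class or came through cell makeup. It set 1757 tissue cells (NR1, NR2 and GRN) with 17378038 reads against 269 culture cells (VT1) with 7329953 reads. Of the culture's 23 predicted doublets 18 were in VT1 and stayed in these sums. Without predicted doublets the interneuron list had −0.81 and the progenitor list −0.88, both still apart from the random lists. The oligodendrocyte precursor list had −0.49, no longer apart. The doublet rule recovered 19.8% of simulated pairs of different classes, so these values cannot exclude doublets as a source. The interneuron list stayed lower in tissue, with a median of −1.09 (−1.22 to −0.72, percentile 0.01) and 10 of 12 members below 0, or 9 of 12 with trimmed-mean scaling, where Gad1 turned. Gad2 (chromosome 2, 22622205 to 22693874) had 2.36 CPM in tissue (1.53 to 3.48) and 37.5 CPM in culture (31.7 to 44.1), a log2 ratio of −3.52, the lowest of the genes with at least 200 reads. Erbb4 had −0.78. The list median was −0.62 within index set A, where 4 members were measured, and −1.14 within index set B, and with a minimum of 200 reads it was −0.21 and no longer stood apart. Against VT1 the list was lower in each tissue cluster, at −1.15 in NR1, −0.78 in NR2 and −1.58 in GRN. The deposited Interneuron set went the other way, at −0.28 ± 1.09 in tissue and −0.67 ± 0.97 in culture, and also within index set A (−0.43 ± 1.13 and −0.54 ± 0.86) and index set B (−0.19 ± 1.06 and −0.58 ± 0.92). All 9 deposited marker sets named for a cell type were higher in the tissue cells of this class, so these scores do not set interneuron genes apart, and they do not agree in direction with the list.

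Genes of neural progenitors were also lower in tissue excitatory neuron-like cells (median −0.85, −1.07 to −0.56, percentile 0.21, 8 of 10 members, or 6 with trimmed-mean scaling, where Nes and Hes5 turned). Sox2, which marks progenitor cells, had 5.41 CPM in tissue (4.08 to 7.04) and 28.5 CPM in culture (23.6 to 34.1), and Sox1 and Pax6 had −1.44 and −1.31. The oligodendrocyte precursor list had −0.62 (−0.92 to −0.40, percentile 1.46, 7 of 8 members), with Lhfpl3 at 61.2 CPM in tissue and 165 CPM in culture. The progenitor list was also raised in AST, 1.79 above the other tissue cells. Both lists were raised in the interneuron-like cluster VT2 over the other culture cells, at 0.45 (7 of 10 members) and 0.33 (8 of 8). Reads from interneuron-like culture cells thus stay open as a source for both lists and were not tested. The endothelial or mural list had −0.64 (−0.93 to −0.39, percentile 0.03), with Tek (−1.42), Abcc9 (−1.39) and Cdh5 (−1.15) lower and Pdgfrb (1.06) higher, whereas the deposited Endothelial and Mural sets were higher in tissue (0.167 ± 0.927 and 0.0398 ± 0.900) than in culture (−0.882 ± 0.803 and −0.548 ± 0.723). Over the alternative settings the endothelial or mural list median ranged from −1.13 to −0.30. All 12 housekeeping genes were higher in tissue (median 0.64, 0.51 to 0.73, percentile 98.6), among them Eef2 (0.93) and Actb (0.80). The endothelial, progenitor and housekeeping lists did not stand apart with promoter regions alone, the progenitor list did not within index set A, and the oligodendrocyte precursor list did not with predicted doublets left out or after thinning. The housekeeping list stood apart in 9 of 15 settings, and not within either index set, with frozen cells alone, without granule-like cells or after thinning.

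Over the pooled class, the list of excitatory neuron genes lay among the random lists (median 0.12, percentile 27.7), and at 0.39 with 10 of 10 members above 0 under trimmed-mean scaling: Camk2a (1.33), Slc17a7 (1.10) and Neurod2 (0.92) were higher in tissue, and Neurod1 was lower at −0.24 but turned with trimmed-mean scaling. The CA1, CA3 and granule lists had 0.44, 0.48 and 0.37, the pan-neuronal list 0.12, the microglia list 0.06 and the Cajal-Retzius list −0.87 (percentile 4.15). The astrocyte, oligodendrocyte, ependymal and fibroblast lists had −0.18, −0.15, −0.09 and −0.17 and each turned above 0 with trimmed-mean scaling. The oligodendrocyte list, with 9 members measured, lay at percentile 47.8, so its difference over all cells was not seen in this class. Within the tissue this list was 3.86 higher in OLI than in the other cells. Postsynaptic genes had a median of 0.34, with Nrgn (1.63), Dlg4 (0.93), Grin2a (0.88) and Grin1 (0.80) higher in tissue. Early genes had 0.30, with Jun (0.86), Arc (0.84), Egr3 (0.74) and Fosb (0.68) higher and Fos (−0.57) lower. Neurite genes had 0.16, with Igfbpl1 (−1.29), Dpysl3 (−0.96) and Gap43 (−0.86) lower and Tubb3 (0.85) higher, and channel genes had 0.14. By tissue cluster against VT1, the excitatory list had 0.51 in NR1 (percentile 98.6), 0.30 in NR2 (72.2) and 0.52 in GRN (83.4), so it stood apart in NR1. The CA1 list had 0.84 in NR1 (percentile 99.95), 0.22 in NR2 (58.6) and −0.76 in GRN (0.55), and the granule list −0.28 (12.8), −0.39 (2.64) and 1.45 (100). NR1 and GRN were told apart by these same lists, so these places were partly built in. The neurite list was at −0.33 in NR1 (percentile 0.23), −0.13 in NR2 (0.38) and 0.15 in GRN (10.8), so its place differed by tissue cluster. The median of all 16394 genes was 0.23 with 65.0% higher in tissue, and 0.50 with 77.8% higher under trimmed-mean scaling.

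Of the genes with the lowest ratios in this class, Tmprss2 (−3.47), Prss54 (−3.27), Slc17a8 (−3.20), Lama1 (−3.01) and Fhl5 (−2.86) followed Gad2. CK137956, Esrp1, Cpb1 and Dach2 had −2.67, −2.66, −2.47 and −2.42. The highest were Smim5 with 18.7 CPM in tissue and 0.409 CPM in culture (0.0844 to 1.20) and Trim31 with a log2 ratio of 3.31. Vsig2 (3.30), Chrm4 (2.77), Pla2g2f (2.76), Topaz1 (2.69), Alox12b (2.43), Tmem54 (2.41), H2-DMb2 (2.30) and Edn2 (2.29) came next. Of these, Smim5, Trim31, Vsig2, Chrm4, Pla2g2f and Tmem54 were also among the 10 highest over all cells.

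The deposited motif scores asked which transcription factor families marked open chromatin in each excitatory neuron-like group. AP-1 motifs, bound by Fos and Jun proteins, scored −1.97 ± 2.08 (SD over 1757 cells) in tissue and 4.14 ± 3.56 (SD over 269 cells) in culture, a difference of −6.10. NFI motifs scored −0.54 ± 0.87 in tissue and 1.81 ± 1.25 in culture. CTCF motifs, bound by a protein that organises chromatin loops, went the other way, with −0.28 ± 1.35 in tissue and −2.32 ± 1.75 in culture, as did EGR motifs (difference 1.10). LIM/DLX homeobox, SOX and MEF2 motifs differed by −1.49, −0.92 and −0.83, and the PU.1, REST, RFX, TEAD, CRE, NEUROD and KLF/SP motifs by −0.81, −0.56, −0.46, −0.19, −0.17, −0.12 and 0.15. The direction was not held between index sets A and B for NEUROD (−0.34 and 0.046) and KLF/SP (0.34 and −0.025), and CRE had −0.004 in set A. The AP-1 difference was −4.92 within index set A and −6.64 within index set B. The CTCF difference was smaller within sets than over the whole class, at 1.83 in set A and 1.56 in set B. Fresh cells of this class had CTCF scores of −0.66 ± 1.08 in set A and −0.65 ± 1.04 in set B. Both lie below the −0.28 over all tissue cells of the class, which include frozen cells. Culture excitatory neuron-like cells of low depth had a lower AP-1 score, 1.09 on average over 26 cells. VT1 cells had a median of 25115 reads, against 8213 in the excitatory neuron-like tissue cells. The other families were not compared at like depth, so depth stays open for their differences too. The shallow culture clusters VT3 and VT4 scored 3.05 ± 2.35 and 3.92 ± 1.88.

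**Figure D4:**
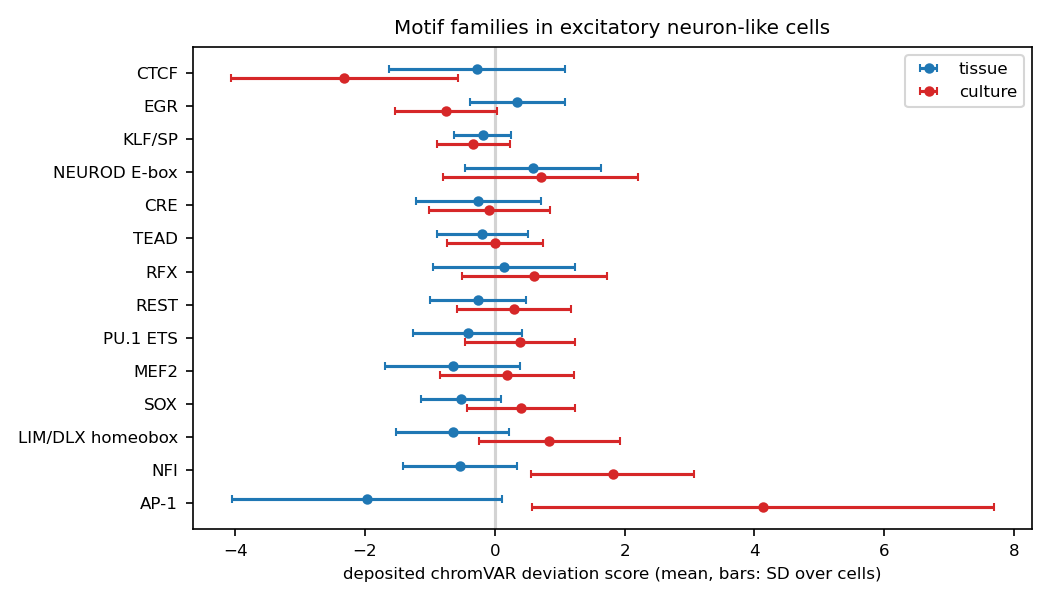
Mean deposited deviation score of each motif family (horizontal axis) in excitatory neuron-like tissue and culture cells, with bars for the SD over cells. AP-1 has the widest gap, from −1.97 to 4.14.

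The comparison within the tissue asked how process genes differed between 1852 neurons and 375 glia, all from the same sample. Postsynaptic genes were more open in neurons for 13 of 16 members (median 1.97, 1.76 to 2.17, percentile 100). Grin2a and Gria1, glutamate receptor genes, had 548 and 428 CPM in neurons against 27.4 and 29.8 CPM in glia, whereas Dlg4 (−0.11) and Homer1 (−0.28) were slightly lower in neurons. Channel genes were higher in neurons for 13 of 14 members (median 1.25, 1.07 to 1.45, percentile 100), among them Cacna1e (3.20), with Kcna2 opposite at −0.72, and the median was 0.41 over promoter regions alone. Neurite genes had 0.39 (0.13 to 0.71, percentile 98.9), with the neurofilament genes Nefl (4.11) and Nefm (3.10) highest. Oligodendrocyte precursor-like cells went the other way, with the neurite list 0.71 above the other tissue cells (percentile 98.4) and a summed 1022 CPM (877 to 1183), against 778 CPM in neurons (760 to 795). Early genes had 0.19 (−0.06 to 0.33, percentile 98.1), with Npas4 (2.95), Bdnf (2.49) and Egr3 (2.01) higher in neurons and Dusp1 (−1.36) and Jun (−0.82) higher in glia. Housekeeping genes had −0.63 (−0.86 to −0.48), with Actb at −1.02, and lay among the random lists (percentile 10.3).

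Fresh and frozen tissue were compared because the series names both. Interneuron-like cells were 4.10% of 1489 fresh cells (3.15 to 5.23) and 8.21% of 804 frozen cells (6.41 to 10.3). Microglia-like cells were 1.21% (0.718 to 1.90) and 3.11% (2.02 to 4.56). In excitatory neuron-like cells, all 10 excitatory neuron genes were higher in fresh tissue, with a list median of 0.25 (0.13 to 0.31, percentile 99.9), and 12 of 14 early genes were higher, with a median of 0.19 (percentile 97.8). Housekeeping genes (0.21, percentile 98.8) and dentate granule genes (0.20, percentile 98.2) were higher in fresh tissue too, so the shift was not particular to excitatory and early genes. Between fresh cells of index sets B and A the early gene median was −0.14 and the granule median 0.17, which are close in size, and the excitatory and housekeeping medians were 0.03 and −0.02. All frozen cells and no fresh cells were in index set D, so freezing and index set cannot be told apart.

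The deposited co-accessibility links of the tissue asked which genes' promoters opened together with other regions. Of 804906 pairs, 67787 (8.42%) had a co-accessibility above 0.1, at a median distance of 126 kb against 169 kb for all pairs. Promoters of early genes had a median of 10 such links against 4 for matched random lists (percentile 99.99) and 3 for all 12695 genes with a promoter region, with the most for Egr3 (22), Ier2 (18) and Junb (17). Excitatory neuron genes and postsynaptic genes each had a median of 8, against 3.5 and 5 for their random lists, with 15 for Slc17a7 and 17 for Grin2a. Housekeeping genes had 7.5 against 3.5, so many links were not a property of neuronal genes alone. Links were summed over all regions of a promoter. The random lists were matched on tissue reads over the gene body and 2 kb upstream, not on reads or regions of the promoter. These percentiles therefore cannot separate a list's links from how open its promoters were. Promoters were joined to promoters in 16.1% of these pairs and to other regions in 31.3%.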

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

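The test of depth for culture clusters VT3 and VT4 was chosen before its result was seen, and every other test below was chosen only after the result was seen. In interneuron-like cells, the dentate granule list was −0.53 (tissue over culture) and the interneuron list 0.48, each opposite in sign to its value in excitatory neuron-like cells, 0.37 and −1.09, and this difference between the classes was not tested. The tissue sample, labelled as fresh, held 827 cells marked frozen, which drew attention because the label does not mention them. The most read region, on chromosome 17 (39843040 to 39848808) over AY036118, Gm26917 and Gm42418, held 1.81% of all reads, a signal outside the genes compared.

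The interneuron list was lower in tissue even within excitatory neuron-like cells, although the deposited Interneuron marker set scored higher in these tissue cells (−0.28 ± 1.09, SD over cells) than in VT1 (−0.67 ± 0.97), so the direction for interneuron genes at large is not settled. Reads from interneuron-like culture cells were examined for Gad2, singled out after the data were seen as the gene with the lowest ratio. Its excess in VT1 over excitatory neuron-like tissue cells was 48.3% (37.9 to 60.5) of its excess in VT2 over the same cells. The other 9 measured list genes that were higher in VT2 than in these tissue cells, which such reads would raise alike, pooled to 16.8% (13.4 to 20.3). Picking Gad2 for its low ratio favours a high percent, so this comparison cannot decide against such reads. Singly, 7 of the 9 lay below Gad2 by their intervals, among them Slc32a1 at 2.31% (−2.03 to 6.94), and Lhx6 (33.0%, 20.8 to 48.8) and Pvalb (32.9%, 17.3 to 54.7) overlapped it. VT1 held 18 of the culture's 23 predicted doublets, and without predicted doublets Gad2 had 45.5% (35.6 to 57.9) and the pool 14.0% (10.6 to 17.5). Such reads, from doublets among other sources, stay open for Gad2 and for the other genes. Neither the PCR index set, as defined here, nor scaling accounts for the list. Its median was −0.62 (−0.96 to −0.06) within set A, −1.14 (−1.44 to −0.75) within set B and −0.85 (−0.97 to −0.46) with trimmed-mean scaling. A batch finer than these sets stays open, because cells were placed in them by the last PCR index alone. A state of the cultured excitatory neurons, their age or the choice of cells that survive plating stays open and untested.

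Culture clusters VT3 and VT4 had few reads per cell and no marker name. Depth alone is unlikely: of 479 VT1 and VT2 cells thinned to 2213 fragments, 3.34% (1.92 to 5.37) came to lie next to VT3 or VT4. They held 56.6% (49.1 to 63.9) of culture cells in index set A, 4.42% (2.38 to 7.44) in set B and 61.0% (55.3 to 66.4) in set C, which is consistent with a difference in the index set or in the material indexed with it. VT3 also had 7.50% of its reads in the 8 heavily read regions, against 3.10% in the culture as a whole, and a median of 16.9% of a VT3 cell's reads and 28.4% of a VT4 cell's lay in called regions, against 45.6% in VT1 and 42.0% in VT2, so low quality of these cells stays open and was not tested. Whether sets held separate cultures is not stated, and no biological explanation was tested.

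AP-1 scores were higher in culture. An effect of the index set, as defined here, is unlikely as the whole cause, since culture exceeded tissue by 4.92 in set A and by 6.64 in set B. Cells were placed in sets by the last PCR index alone, so a batch finer than these sets stays open. Depth is unlikely as the whole cause for VT3 and VT4. Their cells with no more reads than the median tissue cell scored 2.53 ± 1.62 (SD, n = 186) and 3.52 ± 1.67 (n = 77), against −1.83 ± 1.93 over all tissue cells. The tissue cells were not limited by depth here. Of the shallow tissue clusters, OLI and MRG had −0.99 ± 0.69 and −0.64 ± 0.59, and AST and OPC −1.72 ± 0.73 and −1.65 ± 0.84. Part of the gap may therefore come from depth. For the excitatory neuron-like cells depth cannot be told apart in full: those of the culture with no more reads than the median tissue cell of this class scored 1.09 ± 2.54 (n = 26), against −1.97 ± 2.08 in tissue and 4.14 in all VT1 cells, and VT2 cells no deeper than the median tissue cell were no clearer (1.89 ± 2.24, n = 42), so part of the gap may come from depth. A response to culture stays open as well and was not tested.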

How the results depend on the processing

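Alternatives chosen only after the data were seen are those by fresh or frozen material, index set, cluster and heavily read region. The interneuron list stood apart over all cells in 17 of 17 settings (−1.83 to −0.997) and in excitatory neuron-like cells in 14 of 15, where the exception was the minimum of 200 reads (−0.21). The oligodendrocyte list over all cells also lost its place without the lowest 20% of cells, and the progenitor list after thinning. None of the 11 lists that stood apart over all cells or in excitatory neuron-like cells changed its sign in these settings. Over the values of all lists 527 of 632 stayed within the counting interval of the main value, and over named genes 2455 of 3039. Of the other reported values 69 of 84 were labelled unchanged, by unlike rules. Shares and neuron-glia medians had to stay within the main interval. The number of lists that stood apart had to stay within a fold limit, and median depths had to be equal. Each sample's own table gave median depths of 5968.5 reads in tissue and 9939 in culture. Leaving out the lowest 20% of cells by depth gave 81.2% excitatory neuron-like cells in tissue, and 39.2% with 34.4% interneuron-like cells in culture. Own clusters at resolution 0.5 gave 7.98% interneuron-like cells in tissue. By index set A, B and C, the culture had 20.3%, 49.7% and 21.6% excitatory neuron-like and 23.1%, 45.9% and 17.5% interneuron-like cells, and without set B 21.1% and 19.5%. Promoter regions alone gave 0.41 for channel genes between neurons and glia. Beyond the use of fewer cells or regions, the cause was not tested. The motif search in sequence and its 3 alternatives were not run, because a genome sequence was not used here. No paired analysis was possible because each group had 1 sample. Within index set A the 39 excitatory neuron-like culture cells left 4 interneuron genes measured.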

Other observations

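The co-accessibility links were not part of any planned comparison, and no test was run on them. The deposited networks of linked regions in tissue numbered 2064 and held 47788 regions, with a median size of 5 and the largest at 385. Neural progenitor genes had a median of 5 links per promoter (percentile 99.3), and CA1, CA3 and granule genes 3 each. The random lists behind this percentile were not matched on promoter reads. Regions over Gm10800 on chromosome 2 (98666104 to 98667409) and Gm21738 on chromosome 14 (19415624 to 19419624) were read more in culture, with log2 ratios of −2.11 and −2.62.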
